A study of Mus musculus with 6 samples.

How the data were processed

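Bulk RNA-seq was done on type 1 innate lymphoid cells (ILC1s) sorted from the liver of C57BL/6 mice aged 5 weeks. The design holds 1 library of ILC1s bearing the receptor Ly49E and 2 libraries of ILC1s lacking it, with 3 µg of RNA as input for each and an NEBNext Ultra kit of unstated strandedness. The series text speaks of a further Ly49E- sample, which is not in the sample list and is not analysed here. Droplet single-cell RNA-seq (10x Genomics) was done on group 1 ILCs, gated as CD45+ NK1.1+ NKp46+ CD3- CD19-, of mice aged 6 to 8 weeks, in 2 liver libraries and 1 spleen library. The title of the second liver library names the spleen, while its source name and tissue name the liver, and it was treated as liver. The labels do not say whether libraries came from separate animals or pools, so no p-value below is known to measure the spread between animals. Where both classes came from each liver library, p-values per gene rest on counting error and a spread between the 2 liver libraries that was largely shared over genes. They say little about how far a gene's own difference varied between these libraries. In the bulk and organ comparisons the spread came from the replicated group alone. The binomial test is across genes.

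For the bulk libraries the labels name build mm9, HISAT2 2.0.5, featureCounts 1.5.0-p3 and edgeR 3.18.1 without their order. The deposited bulk table holds raw read counts per gene, with the authors' log2 fold change, their log2 mean CPM and their unadjusted p-value beside them. It lists 11024 genes, the lowest with 296 reads over the 3 libraries, so that genes with fewer reads were already missing. The authors' own call column marks 251 genes as higher and 1156 as lower in Ly49E+ ILC1s. Spreadsheet date forms replaced 16 gene symbols, which could not be named. For the single cells the labels name build mm10, Cell Ranger 2.1.1 and Seurat 3.0, while the matrix headers of liver replicate 1 and the spleen library give Cell Ranger 3.1.0. The deposited single-cell matrices hold UMI counts per gene and barcode for all 737280 barcodes, not filtered for cells. Liver replicate 1 and the spleen library list 31053 genes and liver replicate 2 lists 27998, so liver replicate 2 was processed differently by the authors. The 27514 gene identifiers found in all 3 matrices were used.

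Cells were called in each library as barcodes above 1/10 of the 99th percentile of the top 3000 barcodes, with at least 500 genes and at most 10% mitochondrial UMIs. Scrublet within scanpy 1.11.5 predicted doublets with an assumed rate of 0.008 per 1000 cells, and these were removed: 16 barcodes (0.874%) in liver replicate 1, 73 (2.17%) in liver replicate 2 and 31 (1.44%) in the spleen library. Each library was clustered on its own with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1. A cluster was named from fixed markers by the balance of ILC1 over NK markers, the mean log2(CPM + 10) of the former minus that of the latter. It was ILC1-like with a balance above 0 and at least 3 ILC1 markers detected in 10% of its cells, and NK-like with a balance of -2.5 or lower and at least 3 NK markers so detected. Clusters between these bounds, with more genes of another marker set among their 10 leading genes, with another set enriched by over 1.5 on the log2 scale, or of low depth without class markers among their leading genes, stayed unnamed. The marker genes were fixed before the data were examined, but the rule and its bounds were set after the clusters were seen, and they replaced a first, symmetric bound. Cells left unnamed made up 4.19% of liver replicate 1, 35.95% of liver replicate 2 and 19.84% of the spleen library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 were used.

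Differences were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided), after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment at 0.05. The bulk read counts were compared between the 1 Ly49E+ and 2 Ly49E- libraries. UMI counts were summed per library and class for 3 further comparisons. ILC1-like and NK-like cells of the liver were compared with the library as a block, and so were ILC1-like liver cells with and without a Klra5 UMI (Klra5 encodes Ly49E). NK-like cells of the 2 liver libraries were compared with those of the spleen library without a block. Each fit had 1 residual degree of freedom, and the lone Ly49E+ and spleen libraries were assumed to vary like the libraries they were compared with. The common biological coefficient of variation was 0.147 in the bulk fit, 0.0687 between the cell classes, 0.281 between the organs and 0.0433 between the Klra5 classes. Fold changes are log2. Each SE is the absolute fold change divided by the square root of the F statistic of the test. It thus restates the test and does not measure the spread between libraries. CPM values are counts scaled by the TMM-adjusted library total, and values per library use a prior count of 2. Where the libraries gave opposite signs, or a library alone differed from the fitted value by over 1.5 times, their values follow as "by library": liver replicate 1 and then 2 or, in the bulk, against Ly49E- replicate 1 and then 2. These depend on the prior count where a class had few UMIs. No paired analysis was possible because the bulk Ly49E+ group and the spleen have 1 library each, while the block pairs both classes of each liver library. The test was run on simulated data of the same sizes with 100 genes changed 2-fold and 100 changed 4-fold. Counts were drawn with the dispersion trend of the same fit, and lone libraries were given the spread of the others. The assumptions of the test thus held by construction. It found 62 and 99 of the changed genes in the bulk design, 71 and 93 between the cell classes, 4 and 39 between the organs, and 52 and 87 between the Klra5 classes. False calls numbered 5, 6, 3 and 2. These counts do not show how the test behaves where its assumptions fail. Replicates were checked for copies: chi-square per gene was 99.4 between the Ly49E- libraries, 20.1 between the ILC1-like sums and 21.9 between the NK-like sums of the liver libraries.

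Before the data were examined, 27 gene lists were fixed. They cover the ILC1 signature, NK signature, cytotoxic effectors, cytokines and chemokines, Ly49 receptors, other NK receptors, homing and adhesion, transcription factors, cytokine receptors, immediate early and stress genes, proliferation, interferon-stimulated genes, fetal haematopoiesis genes, ribosomal protein genes and mitochondrial mRNAs. The others hold markers of T cells, ILC2s and ILC3s, B cells, plasma cells, macrophages and monocytes, neutrophils, dendritic cells, hepatocytes, endothelium, stellate cells and fibroblasts, erythroid cells and platelets, and basophils and mast cells. Medians of lists are of log2 fold changes. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, which called no list in any of the 4 comparisons. With 1 residual degree of freedom this second test could hardly call any list. Even the ILC1 and NK signatures between the cell classes, which are circular, had an adjusted p of 0.4065 in it. Its values therefore cannot decide for or against a list. The genes to be named were also fixed by rule before the data were examined. Per comparison they were up to 10 rising and 10 falling genes past the threshold with the largest fold change, among those with at least 20 CPM in the higher group and the same direction in every library. Where none passed, the 5 largest each way were taken as values. Genes without a proper symbol, ribosomal protein and mitochondrial genes, antigen receptor segments, class markers and, in the Klra5 comparison, Klra5 were left out. Up to 4 of the most abundant members of each list, Klra5 everywhere and other list members past the threshold could be named too.

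Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 was read as allowing up to 3 counts. Intervals and limits cover counting error only. Klra5 shares were also taken after each cell was thinned to 2000 UMIs. The bulk and single-cell fold changes were compared over genes tested in both, with an exact two-sided binomial test and Spearman's coefficient across genes, which are not independent replicates. The alternatives fixed before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0, the likelihood ratio test, no replicate block, leaving out each replicated library, doublets kept, resolutions 0.5 and 2, at most 5% mitochondrial UMIs, a minimum of 1000 UMIs, classes per cell, 2 Klra5 UMIs, thinning and the estimated correlation. After seeing the data 3 were added: a further spleen cluster counted as NK-like, the Klra5-rich clusters alone, and the bulk genes at 20 CPM or more in ILC1-like liver cells. Gene positions came from GENCODE vM21 on mm10. Reads of close paralogs (the Ly49, Mup, Serpina1 and globin genes) can be shared among them, and this was not resolved here.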

Results

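Liver ILC1s were profiled by bulk RNA-seq as 1 Ly49E+ and 2 Ly49E- libraries, and group 1 ILCs by single-cell RNA-seq in 2 liver libraries and 1 spleen library. The bulk libraries held 58673770 counted reads for Ly49E+ cells and 70076361 and 49443529 for Ly49E- replicates 1 and 2. After filtering, 1815 cells of liver replicate 1, 3291 of liver replicate 2 and 2127 of the spleen were kept, with medians of 4274, 3849 and 3483 UMIs and of 1563, 1394 and 1362 genes per cell. Barcodes under 100 UMIs, which hold mostly free RNA, took 21.7%, 5.49% and 15.5% of all UMIs in the same order.

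The bulk comparison asked which transcripts differ between liver ILC1s with and without Ly49E. Klra5, which encodes Ly49E and lies on chromosome 6 (mm10, 129898996 to 129917650), stood at 735 CPM in the Ly49E+ library against 10.1 and 2.59 in the Ly49E- libraries, a log2 fold change of 6.83 (SE 0.61, adjusted p = 0.000637). Granzyme A and B, serine proteases that kill target cells, rose with it: Gzma (chromosome 13, 113093825 to 113100981) from 1080 and 705 to 3231 CPM, by 1.86 (SE 0.28, adjusted p = 0.00375), and Gzmb (chromosome 14, 56258838 to 56262260) from 1629 and 1041 to 4285 CPM, by 1.68 (SE 0.29, adjusted p = 0.00709). Il7r, the interleukin-7 receptor chain (chromosome 15, 9505788 to 9530176), went the other way, from 54.1 and 50.9 to 13.7 CPM, with a log2 fold change of -1.94 (SE 0.17, adjusted p = 0.000625). Tmem176a and Tmem176b, neighbouring genes on chromosome 6 (48840919 to 48847071 and 48833818 to 48841496), fell with it, with log2 fold changes of -2.42 (SE 0.18, adjusted p = 0.000409) and -2.37 (SE 0.19, adjusted p = 0.000449).

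After Klra5, the largest rises under the naming rule (at least 20 CPM in the higher group) were Mup7 (3.84), the phosphatase subunit Ppp2r2c (3.81), Fga (3.43), Fgg (3.20), the secreted serine protease Htra3 (3.20), and Ambp, Fgb, Serpina1e and Apob (between 3.09 and 3.12). Of these, Mup7, Ambp, Serpina1e, Apob and the fibrinogen genes Fga, Fgb and Fgg are known as products of hepatocytes. Htra3 (chromosome 5, 35652023 to 35679782) went from 12.6 and 6.68 to 89.2 CPM (SE 0.31, adjusted p = 0.000720). The largest falls under the same rule were Saa3 (-6.24), Pf4 (-5.86), Serpinb2 (-5.67), Alox15 (-5.50), C1qb (-4.89), C1qa (-4.76), Prg4 (-4.75), Cd5l (-4.67), C4b (-4.65) and C1qc (-4.55). C1qa, C1qb and C1qc, the complement C1q chains, and Cd5l are known as macrophage products. The cell source of the other falls was not tested, and the macrophage and monocyte marker list had a median of -3.39 in the same comparison. With DESeq2, Mup7 (adjusted p = 0.139), Fga (adjusted p = 0.0674) and Fgb (adjusted p = 0.100) did not pass.

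Among 13 measured cytotoxic effector genes, 7 rose, 1 fell and 5 did not pass the test (9 rose and 1 fell when adjusted over the list alone). A median of 0.77 went with a camera adjusted p = 0.000313 (adjusted p = 0.707 with an estimated correlation). The members that rose were Gzma (1.86), Gzmb (1.68), Gzmc (1.00), Cst7 (0.93), Prf1 (0.87), Tnfsf10 (0.86) and Fasl (0.77), and the lysosomal membrane protein gene Lamp1 fell (-1.59). Among 28 other NK receptor genes, 10 rose, 3 fell and 15 did not pass the test (13 rose and 3 fell when adjusted over the list alone). The median was 0.43, with a camera adjusted p = 0.00316 (adjusted p = 0.707 with an estimated correlation). Those that rose included Pdcd1 (2.34), Tigit (1.54), Lag3 (0.89) and Cd7 (0.83), and those that fell were Havcr2 (-2.69), Ctla4 (-1.65) and Fcgr3 (-1.32). Of 14 cytokine and chemokine genes, 3 rose, 1 fell and 10 did not pass the test (4 rose and 1 fell when adjusted over the list alone). Around their median, 0.40, camera gave an adjusted p = 0.0496 (adjusted p = 0.707 with an estimated correlation). Csf1 (1.15), Tnfsf8 (1.05) and Ccl4 (0.70) rose and Tnf (-0.82) fell, while Ifng, encoding interferon gamma, stood at 0.39 (SE 0.19, adjusted p = 0.214). Hepatocyte genes were higher in the same Ly49E+ library, with a list median of 2.81, and markers of macrophages, which also express Lamp1, Havcr2, Fcgr3 and Tnf, were lower, with a list median of -3.39. Ribosomal protein genes had a median of -0.37.

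The ILC1 signature split: of 14 genes, 6 rose, 3 fell and 5 did not pass the test (7 rose and 4 fell when adjusted over the list alone). The list median, 0.46, had a camera adjusted p = 0.584. The mean was -0.05, of opposite sign to the median and the test. Itga1, the integrin chain CD49a, rose (1.15), as did Gpr55 (0.88), Zfp683 (0.84), Tnfsf10 (0.86), Il21r (0.78) and Cd200r1 (0.77), while Tmem176a (-2.42), Tmem176b (-2.37) and Il7r (-1.94) fell. In the NK signature, 15 genes were measured, of which 2 rose, 6 fell and 7 did not pass the test (2 rose and 9 fell when adjusted over the list alone). A median of -1.04 went with a camera adjusted p = 0.0138 (adjusted p = 0.707 with an estimated correlation). Gzma and Prf1 rose, and Zeb2 (-2.31), Cx3cr1 (-2.30), Ly6c2 (-2.20), S1pr5 (-1.90), Itgam (-1.87) and Emp3 (-1.35) fell. Zeb2, Cx3cr1, Ly6c2 and Itgam are also made by monocytes and macrophages. For the 9 Ly49 receptor genes other than Klra5, 1 rose, 2 fell and 6 did not pass the test (2 rose and 2 fell when adjusted over the list alone). The median was -0.03 (by library -0.22 and 0.20), with a camera adjusted p = 0.598. Klra9 (0.83) rose and Klra2 (-2.72) and Klra6 (-3.14) fell. Cytokine receptors numbered 26, of which 2 rose, 11 fell and 13 did not pass the test (3 rose and 11 fell when adjusted over the list alone). Around their median, -0.16 (by library -0.26 and -0.11), camera gave an adjusted p = 0.0140 (adjusted p = 0.707 with an estimated correlation). Falls in Il7r (-1.94), Il18r1 (-1.54), Kit (-1.90) and Il2ra (-1.04) stood beside falls in Ifngr2 (-2.35), Il6ra (-2.14) and Il10ra (-1.63), which macrophages also express, and Il12rb2 (0.91) and Il21r (0.78) rose. The macrophage marker median was -3.39, the hepatocyte gene median 2.81 and the ribosomal protein gene median -0.37 in the same comparison.

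Among 23 homing and adhesion genes, 3 rose, 8 fell and 12 did not pass the test (5 rose and 9 fell when adjusted over the list alone). The list median, -0.26 (by library -0.17 and -0.28), had a camera adjusted p = 0.146. Cd69, an early activation marker that holds lymphocytes in tissue, and the chemokine receptor Cxcr3 rose (1.09 and 0.70), and Cxcr4 (-2.25), Ccr2 (-2.07), Cd9 (-0.98) and Cd44 (-0.73) fell. Ccr2 went from 276 and 439.8 to 85.2 CPM. Of 27 transcription factors, 4 rose, 4 fell and 19 did not pass the test (6 rose and 9 fell when adjusted over the list alone). A median of -0.28 went with a camera adjusted p = 0.444. The factors Id3 (-1.94), Klf3 (-1.72) and Tcf7 (-1.10) and Zeb2 fell, while Tox (0.96), Zfp683 (0.84), Ikzf3 (0.83) and Zeb1 (0.60) rose, and Tbx21, which encodes T-bet, stood at 0.61 (SE 0.25, adjusted p = 0.155). Interferon-stimulated genes were lower in the Ly49E+ library: of 34, 0 rose, 22 fell and 12 did not pass the test (1 rose and 28 fell when adjusted over the list alone). The median was -1.23, with a camera adjusted p = 5.50e-11 (adjusted p = 0.707 with an estimated correlation). Examples were Ifi27l2a (-2.67), Oasl2 (-2.53), Gbp2 (-1.81) and Irf7 (-1.05), and Irf1 (-0.28) and Gbp4 (0.37) did not pass. Beside each of these falls stood the lower macrophage markers (list median -3.39) and a ribosomal protein gene median of -0.37 in the Ly49E+ library.

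Markers of other cells moved with Ly49E. All 14 measured macrophage and monocyte markers fell, with a median of -3.39 and a camera adjusted p = 1.86e-36 (adjusted p = 0.707 with an estimated correlation). Lyz2, lysozyme, fell from 4306 and 7144 to 889.5 CPM and Csf1r, the macrophage growth factor receptor, from 639 and 849 to 118 CPM. For 13 dendritic cell markers, 1 rose, 9 fell and 3 did not pass the test (2 rose and 10 fell when adjusted over the list alone). Around their median, -1.58, camera gave an adjusted p = 2.98e-09 (adjusted p = 0.707 with an estimated correlation). The class II genes H2-Ab1 (-2.60) and Cd74 (-2.27) fell and Siglech (1.22) rose. Endothelial markers numbered 5, of which 0 rose, 4 fell and 1 did not pass the test. The list median, -2.54, had a camera adjusted p = 3.18e-06 (adjusted p = 0.707 with an estimated correlation). Stab1 (-3.86) fell and Pecam1 (0.34) did not pass. Hepatocyte genes rose: of 16, 14 rose, 1 fell and 1 did not pass the test. A median of 2.81 went with a camera adjusted p = 4.98e-10 (adjusted p = 0.707 with an estimated correlation). Alb, albumin, went from 47.4 and 14.1 to 214 CPM, and the gene that fell, Apoe (-3.11), is also made by macrophages. In ILC1-like liver cells none of the 14 macrophage markers reached 20 CPM, against 1 of the 16 hepatocyte genes (Trf) and 3 of the 13 dendritic cell markers (Bst2, Cd74 and Cst3).

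T cell markers numbered 11, of which 3 rose, 1 fell and 7 did not pass the test (5 rose and 2 fell when adjusted over the list alone). The median was 0.43 (by library 0.22 and 0.78), with a camera adjusted p = 0.157. Cd8a (1.38), Cd3e (1.09) and Bcl11b (0.80) rose and the co-stimulatory receptor gene Cd28 (-1.68) fell. Neutrophil markers numbered 6, of which 0 rose, 3 fell and 3 did not pass the test. Around their median, -0.84 (by library -0.55 and -1.03), camera gave an adjusted p = 0.0496 (adjusted p = 0.707 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, fell (-2.49). Of 12 B cell markers, 0 rose, 0 fell and 12 did not pass the test. The list median, 0.08 (by library 0.23 and -0.08), had a camera adjusted p = 0.431. Of 4 plasma cell markers, 0 rose, 0 fell and 4 did not pass the test. A median of 0.15 (by library 0.20 and 0.01) went with a camera adjusted p = 0.564. Among 3 erythroid and platelet genes, Pf4 fell and 2 did not pass the test. Their median was 0.04, while their mean was -1.82 and the test pointed down (camera adjusted p = 0.0104; adjusted p = 0.707 with an estimated correlation). Without Ly49E- replicate 1 the median was -0.65 and without replicate 2 it was 1.39. Lists with fewer than 3 measured members were not tested as sets. In them Lta4h of the ILC2 and ILC3 markers rose (0.63), while Ecm1 of the stellate cell markers (-3.62) and Kit of the mast cell markers fell. Hilpda (-0.68), Hdc (-1.18) and the fetal haematopoiesis genes Hmga1 (-0.36) and Arid3a (-0.01, by library 0.09 and -0.11) did not pass. Of 26 ribosomal protein genes, 0 rose, 3 fell and 23 did not pass the test (0 rose and 0 fell when adjusted over the list alone). The median was -0.37, with a camera adjusted p = 0.0205 (adjusted p = 0.802 with an estimated correlation). Of 30 immediate early and stress genes, 5 rose, 3 fell and 22 did not pass the test. Around their median, 0.15 (by library 0.24 and -0.06), camera gave an adjusted p = 0.146. Hspa1b (1.17) rose and Atf3 (-2.07), Ier3 (-2.04) and Nr4a1 (-0.81) fell. Of 11 mitochondrial mRNAs, 0 rose, 0 fell and 11 did not pass the test. The list median, 0.13 (by library -0.13 and 0.30), had a camera adjusted p = 0.453.

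In all, edgeR called 451 genes higher and 1355 lower in Ly49E+ ILC1s among all genes of the deposited table, and 3247 had an unadjusted p under 0.05. Of the 816 called genes that were also tested in the single cells, 510 reached 20 CPM in ILC1-like liver cells, and 206 of these were higher and 304 lower. That limit was chosen after seeing the data. The Ly49E+ group rests on 1 library, so its own spread was not measured.

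**Figure D1:**
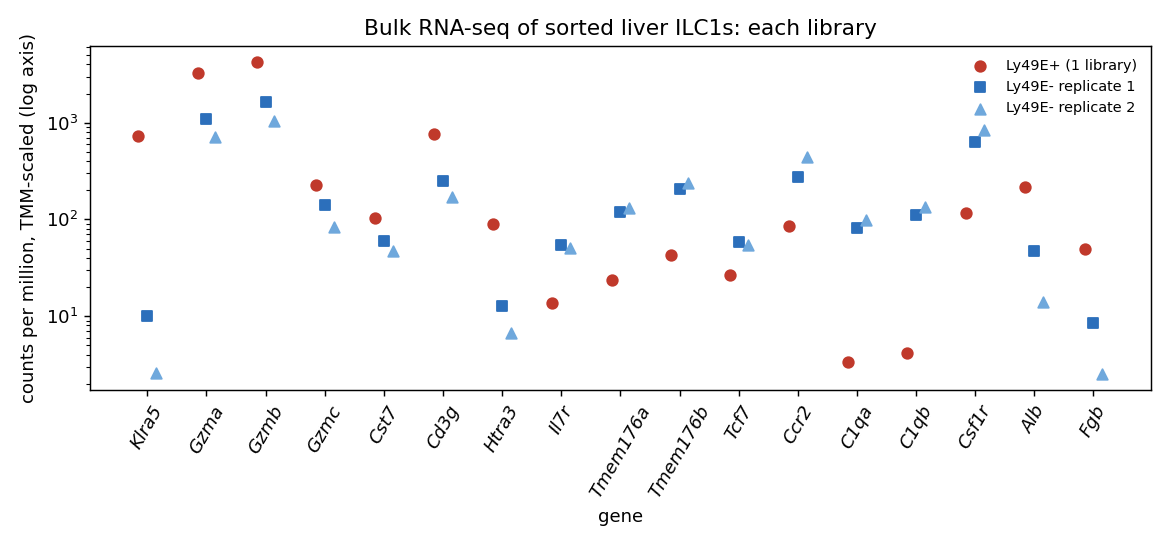
CPM (TMM-scaled, log axis) of 17 genes in each bulk library; red circles are the Ly49E+ library, blue squares and light blue triangles are Ly49E- replicates 1 and 2. Klra5 stood at 735 CPM in the Ly49E+ library and at 10.1 and 2.59 in the Ly49E- libraries, while Csf1r stood at 118 against 639 and 849.

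The single cells were asked how the liver and spleen divide into ILC1-like and NK-like cells within the gate of NK1.1+ NKp46+ cells lacking CD3 and CD19. ILC1-like cells made up 36.6% (637 of 1739; 95% interval 34.4 to 38.9) of the ILC1-like and NK-like cells of liver replicate 1, 51.5% (1085 of 2108; 49.3 to 53.6) of liver replicate 2 and 6.39% (109 of 1705; 5.28 to 7.66) of the spleen library. The ILC1-like cells formed a pair of clusters in each liver library. The leading genes of the first were Tmem176b, Tmem176a and, in liver replicate 2, Il7r (323 cells of liver replicate 1 and 463 of liver replicate 2). The second was led by Cd3g, Gzmc and Klra5 (314 and 622 cells). The spleen held 1 ILC1-like cluster (109 cells), led by Tmem176b, Ckb, Tmem176a and Il7r. Between liver replicate 1 and the spleen library, which share a Cell Ranger version, the shares were 36.6% and 6.39%. The liver share moved with the clustering and the class rule (liver replicate 1 from 28.4% to 43.6%), and with a minimum of 1000 UMIs no spleen cluster was named ILC1-like. With 1 spleen library, no test across libraries was made.

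Within the liver, ILC1-like cells were compared with NK-like cells to describe the classes. Granzyme C, a cytotoxic protease, was higher in ILC1-like cells: Gzmc (chromosome 14, 56231441 to 56234656) stood at 412 and 354 CPM in the 2 libraries against 8.00 and 18.5 in NK-like cells, a log2 fold change of 4.85 (SE 0.13, adjusted p = 5.98e-276). Cd3g, a chain of the T cell receptor complex (chromosome 9, 44969572 to 44980431), stood at 616 and 1326 against 23.1 and 72.6 CPM, a rise of 4.41 (SE 0.12, adjusted p = 1.58e-288). The gate excluded cells with surface CD3. The other largest rises under the naming rule, which leaves out class markers, were Cd200r2 (5.74), P2rx7 (5.42), Gpr34 (5.25), Adam19 (5.00), Atp8a2 (4.81), Zmat4 (4.61), Art2b (4.54, by library 4.85 and 2.67) and Asb2 (4.41). The largest falls under that rule were Serpinb9b (-6.29), Car5b (-5.55), As3mt (-5.34), Khdc1a (-5.21), Cmklr1 (-5.11), Khdc1c (-5.07), Rgs16 (-5.04), Cym (-5.00) and Zfhx3 (-4.96). Gp1bb, also among the largest falls, had 3 UMIs in ILC1-like and 173 in NK-like cells, a ratio of 51.1 in favour of NK-like cells (95% counting interval 17.2 to 250.2).

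All 14 genes of the ILC1 signature rose and all 18 of the NK signature fell, with medians of 3.81 and -4.25, but most of these genes define the classes, so their direction is circular (camera adjusted p = 2.37e-28 and 5.53e-42; adjusted p = 0.406 for both with an estimated correlation). The 7 Ly49 receptor genes, of which Klra4 and Klra8 are class markers, all fell, with a median of -3.24 and a camera adjusted p = 6.91e-19 (adjusted p = 0.406 with an estimated correlation). Klra7 (-4.05), Klra3 (-3.24) and Klra9 (-2.07) were among them. Cytotoxic effectors divided: of 16, 5 rose, 11 fell and 0 did not pass the test. A median of -0.86 went with a camera adjusted p = 0.00359 (adjusted p = 0.442 with an estimated correlation). Gzmc (4.85) and Gzmb (0.62, by library 0.25 and 0.99) and the class marker Tnfsf10 (3.83) rose, while Gzmm (-3.39), Prf1 (-2.23) and Gzma (-1.19) fell. Cytokines mostly rose: of 13, 9 rose, 2 fell and 2 did not pass the test. The median was 1.66, with a camera adjusted p = 3.28e-06 (adjusted p = 0.442 with an estimated correlation). Tnf (3.30), Csf2 (2.53), Ltb (2.31), Xcl1 (1.82) and Il2 (1.66) were higher and Ccl5 (-0.75) lower in ILC1-like cells. Gene groups that can reflect handling or RNA quality differed between the classes too. Both classes came from the same libraries, and the cause was not tested. Of 29 immediate early and stress genes, 15 rose, 4 fell and 10 did not pass the test (16 rose and 4 fell when adjusted over the list alone). Around their median, 0.52 (by library 0.53 and 0.21), camera gave an adjusted p = 7.72e-05 (adjusted p = 0.521 with an estimated correlation). Hspa1b (2.37), Egr1 (1.60), Gadd45b (1.55) and Jun (1.33) rose. Of 13 mitochondrial mRNAs, 0 rose, 10 fell and 3 did not pass the test. The list median, -0.41, had a camera adjusted p = 0.000120 (adjusted p = 0.521 with an estimated correlation). Of 26 ribosomal protein genes, 0 rose, 12 fell and 14 did not pass the test (0 rose and 15 fell when adjusted over the list alone). A median of -0.25 (by library -0.16 and -0.34) went with a camera adjusted p = 0.000155 (adjusted p = 0.613 with an estimated correlation).

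Of 25 other NK receptor genes, 12 rose, 4 fell and 9 did not pass the test (13 rose and 4 fell when adjusted over the list alone). The median was 0.23 (by library 0.14 and 0.23), with a camera adjusted p = 0.00580 (adjusted p = 0.442 with an estimated correlation). Lag3 (4.25), Cd226 (2.74), Cd7 (2.47) and Ctla4 (2.11, by library 2.62 and 0.96) rose and Klrg1 (-3.87) fell. Among 22 homing and adhesion genes, 8 rose, 13 fell and 1 did not pass the test. Around their median, -0.85, camera gave an adjusted p = 0.00104 (adjusted p = 0.442 with an estimated correlation). Receptors that hold cells in tissue, Cxcr6 (5.64), Itga1 (4.44) and Cd69 (1.03), rose with Cxcr3 (2.43), and receptors of recirculating cells, Cx3cr1 (-5.68), Sell (-4.83) and S1pr1 (-4.36), fell. Cxcr6, Itga1, Cx3cr1 and Sell are class markers. For 29 transcription factors, 8 rose, 16 fell and 5 did not pass the test. The list median, -0.27 (by library -0.16 and -0.20), had a camera adjusted p = 0.0200 (adjusted p = 0.462 with an estimated correlation). Maf (1.86), Ahr (1.85) and Tox (1.43) rose, as did Zfp683, with 63 UMIs in ILC1-like against 1 in NK-like cells, a ratio of 71.1 (95% counting interval 12.3 to 2852), and Eomes (-5.22) and Zeb2 (-5.17), both class markers, and Tcf7 (-1.47, by library -0.79 and -2.12) fell. In the list of 22 cytokine receptors, 11 rose, 6 fell and 5 did not pass the test (11 rose and 7 fell when adjusted over the list alone). A median of 0.31 (by library 0.29 and 0.15) went with a camera adjusted p = 0.121. Il2ra (2.91) and Il21r (2.69) and the class marker Il7r (3.02) rose, and Il18r1 (-1.43) and Il18rap (-1.53), the chains of the interleukin-18 receptor, fell. Of 4 T cell markers, 3 rose, 0 fell and 1 did not pass the test. The median was 1.30 (by library 0.63 and 1.61), with a camera adjusted p = 0.0138 (adjusted p = 0.442 with an estimated correlation). Bcl11b (2.65) and Cd3e (2.15, by library 0.78 and 2.51) were higher in ILC1-like cells, and the fitted rise of Cd3d (0.44, by library -0.08 and 0.74) came from liver replicate 2. Of 6 dendritic cell markers, 5 rose, 0 fell and 1 did not pass the test. Around their median, 2.16 (by library 2.21 and 1.29), camera gave an adjusted p = 0.000107 (adjusted p = 0.442 with an estimated correlation). The class II genes Cd74 (3.29) and H2-Aa (3.03) were among them. Of 5 erythroid and platelet genes, 0 rose, 0 fell and 5 did not pass the test. The list median, -0.08 (by library -0.12 and 0.01), had a camera adjusted p = 0.820. Beside these groups stood the medians of 0.52 for immediate early and stress genes, -0.41 for mitochondrial mRNAs and -0.25 for ribosomal protein genes.

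With the library as a block, edgeR called 1346 genes higher and 1400 lower in ILC1-like cells among 9576 tested, and 3551 had an unadjusted p under 0.05. Without the replicate block 173 rose and 159 fell, Art2b (adjusted p = 0.0776) and Gp1bb (adjusted p = 0.0626) not among them, and with DESeq2 924 were called, 480 of them higher; each of these genes was also called with the block, in the same direction.

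NK-like cells of the liver were set against those of the spleen to ask what differs by organ. No gene passed in edgeR among 9753 tested, so the following are values; 191 genes had an unadjusted p under 0.05, and DESeq2 also called 0 genes (56 with an unadjusted p under 0.05). Jun, an immediate early transcription factor, stood at 706 and 421 CPM in the liver libraries and at 1973 in the spleen library, a log2 fold change of -1.81 (SE 0.29, adjusted p = 0.864). Globin mRNAs stood higher in liver: Hba-a1 at 5.58 (SE 1.17), Hbb-bs at 5.26 (SE 0.93), Hba-a2 (5.25, by library 5.95 and 3.14) and Hbb-bt (4.44, by library 5.13 and 2.47). Within the pair that shares a Cell Ranger version, liver replicate 1 against spleen, the log2 ratios were -1.48 for Jun, 6.32 for Hba-a1 and 6.00 for Hbb-bs, against -2.23, 3.28 and 3.53 for liver replicate 2. RLE factors (188 with an unadjusted p under 0.05) and no filter (124) also gave 0 calls in edgeR. Srp54c had 4.79, from liver replicate 2 alone (89.3 CPM against 1.83 in liver replicate 1 and 1.62 in spleen). The other values were Hist1h3a (-1.48, by library -0.96 and -2.20), Kif13b (-1.44, by library -0.62 and -3.31) and Fam120b (-1.41, by library -0.84 and -2.23), and Tmem254a (-1.51) had 0 UMIs in liver replicate 2 and a log2 ratio of -0.51 in liver replicate 1.

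Of 19 lists tested, camera called 5 at the preset correlation. The 5 erythroid and platelet genes tested had a median of 5.26 (by library 5.95 and 3.14), and all 5 were called when adjusted over the list alone (camera adjusted p = 5.31e-29; adjusted p = 0.809 with an estimated correlation). The 12 ILC1 signature genes tested in NK-like cells had a median of 1.38 (by library 1.27 and 0.79) with 0 called (camera adjusted p = 4.16e-10; adjusted p = 0.809 with an estimated correlation), in liver libraries whose ILC1-like share was also higher. The spleen class left out an unnamed cluster of 388 cells with NK markers, and with it counted as NK-like, a choice made after seeing the data, this median was 0.75 (by library 0.50 and 0.27), with a camera adjusted p = 0.00161 (adjusted p = 0.789 with an estimated correlation). Of 29 immediate early and stress genes, 4 fell when adjusted over the list alone and 0 over all genes, with a median of -0.40 (by library -0.39 and -0.98), with a camera adjusted p = 2.30e-07 (adjusted p = 0.809 with an estimated correlation). Abundant members were Junb (-0.40, by library -0.25 and -0.56), Nfkbia (-0.72, by library 0.03 and -2.40) and Jund (-0.69, by library -0.39 and -1.07), and the negative value of Nfkbia came from liver replicate 2, since liver replicate 1, which shares a Cell Ranger version with the spleen library, gave 0.03. The 22 proliferation genes had a median of 0.30 (by library 0.07 and 0.35), with a camera adjusted p = 0.000568 (adjusted p = 0.809 with an estimated correlation), and the 16 cytotoxic effectors one of 0.19 (camera adjusted p = 0.0463; adjusted p = 0.809 with an estimated correlation), with Gzmb (0.68, by library 1.05 and 0.18) and Gzma at 0.35. In the NK signature the median was -0.08 (by library 0.08 and -0.06) over 18 genes (camera adjusted p = 0.648), with Klra4 at -0.73 and Klf2 at -0.81. The clusters with proliferation genes among their leading genes stayed unnamed in all 3 libraries and are not in these values. Organ and processing differ together for liver replicate 2, and on simulated data this design found 39 of 100 genes changed 4-fold.

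Klra5 transcripts were then counted per cell to ask which cells carry Ly49E mRNA. A Klra5 UMI was found in 12.9% of ILC1-like cells of liver replicate 1 (82 of 637; 95% interval 10.4 to 15.7) and in 21.4% of liver replicate 2 (232 of 1085; 18.98 to 23.94), at median depths of 4902 and 4110 UMIs. In NK-like cells of the same libraries the share was 2.09% (23 of 1102; 1.33 to 3.12) and 2.93% (30 of 1023; 1.99 to 4.16), at 3744 and 3682 UMIs. Whether these UMIs are background or Klra5 mRNA made by NK-like cells was not tested. Klra5 stood at 103 and 199 CPM in these ILC1-like cells, at 12.9 and 17.6 CPM in the NK-like cells and at 10.4 CPM in NK-like cells of the spleen. At equal depth of 2000 UMIs the ILC1-like shares were 10.1% and 17.7% and the NK-like shares 1.38% and 1.97%. In the spleen library 0 of 109 ILC1-like cells had a Klra5 UMI, which allows a share of up to 2.75% of cells with a UMI, against 1.75% (28 of 1596; 1.17 to 2.53) of NK-like cells. No difference was detectable there, at median depths of 4780 and 3202 UMIs. Of the Klra5-positive ILC1-like cells, 92.7% in liver replicate 1 and 96.1% in liver replicate 2 lay in the cluster led by Cd3g, Gzmc and Klra5. Klra5 was not left out of the clustering, so these shares are partly circular. Outside both classes, an unnamed cluster of liver replicate 2 led by globin and proliferation genes had a Klra5 UMI in 18.0% of its cells (11 of 61; 9.36 to 29.98). In liver replicate 1 the unnamed globin cluster had one in 3.23% (2 of 62; 0.393 to 11.2), and the proliferating cluster in 0 of 14 cells, which allows up to 21.4%. The other unnamed clusters had shares of 3.41% (25 of 733; 2.22 to 4.99) and 2.57% (10 of 389; 1.24 to 4.68) in liver replicate 2 and 1.29% (5 of 388; 0.420 to 2.98) in the spleen, where a proliferating cluster had 0 of 27 (up to 11.1%) and a cluster of 7 cells had 0.

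**Figure D2:**
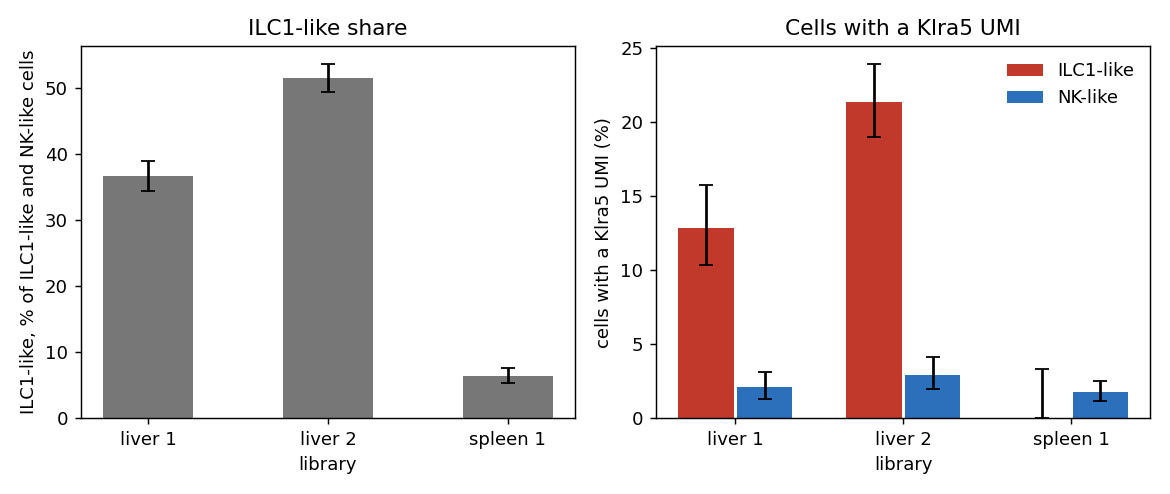
Left, ILC1-like cells as a percentage of ILC1-like and NK-like cells in each library; right, the percentage of ILC1-like (red) and NK-like (blue) cells with a Klra5 UMI; bars are shares and whiskers exact 95% binomial intervals. In the liver 12.9% and 21.4% of ILC1-like cells had a Klra5 UMI against 2.09% and 2.93% of NK-like cells, and in the spleen 0 of 109 ILC1-like cells did.

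ILC1-like liver cells with a Klra5 UMI were compared with those without, as the nearest single-cell counterpart of the sort. The sort went by the receptor and the classes by detected mRNA. Thinning to 2000 UMIs lowered the shares with a Klra5 UMI from 12.9% and 21.4% to 10.1% and 17.7%. Cells without a Klra5 UMI can therefore still hold Klra5 mRNA. Gzma stood at 12450 and 12820 CPM in Klra5-positive cells of the 2 libraries against 3016 and 5716. Its log2 fold change was 1.60 (SE 0.05, adjusted p = 1.06e-180), by library 2.05 and 1.17, a difference that the SE does not cover. Gzmb and Gzmc rose by 1.37 (SE 0.06, adjusted p = 8.69e-118) and 1.08 (SE 0.08, adjusted p = 7.60e-40), the latter by library 1.54 and 0.69. Cd3g rose from 397 and 909.8 to 2240 and 3100 CPM, by 2.08 (SE 0.06, adjusted p = 1.12e-211). Under the naming rule, which asks for at least 20 CPM in the higher class, the largest rise was Htra3, at 4.22 (SE 0.32, adjusted p = 2.55e-36). It was followed by the sulfotransferase gene Sult2b1 (3.05), the genes Actn2 (2.06), Cd3d (2.04, by library 1.34 and 2.15), Htra1 (1.93), AA467197 (1.78) and G0s2 (1.63) and the protease inhibitor gene Serpinb6a (1.52). Il7r went down, from 68.1 and 68.4 to 17.2 and 4.97 CPM, with a log2 fold change of -2.99 (SE 0.31, adjusted p = 1.20e-19), by library -1.92 and -3.53.

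The largest falls under the same rule, which also leaves out class markers, included the oxysterol receptor gene Gpr183 (-3.45), Ramp1 (-2.90) and Emb (-2.70), the co-stimulatory receptor gene Cd28 (-2.41), the class II chaperone gene Cd74 (-2.25), the protease gene Mmp9 (-2.02) and the transcription factor gene Hes1 (-2.02). A further 3 of them had few UMIs in Klra5-positive cells: Krt83 had 1 against 224 in negative cells, a ratio of 50.1 (95% counting interval 8.90 to 1987), Capg had 1 against 128, a ratio of 28.6 (5.05 to 1139), and Tnfrsf25 had 2 against 137, a ratio of 15.3 (4.16 to 128). Cd74 gave a log2 fold change of -0.31 at resolution 0.5, where it did not pass.

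Of 13 cytotoxic effectors, 5 rose, 0 fell and 8 did not pass the test (6 rose and 2 fell when adjusted over the list alone). A median of 0.22 went with a camera adjusted p = 6.93e-32 (adjusted p = 0.637 with an estimated correlation). Gzma (1.60), Gzmb (1.37), Gzmc (1.08, by library 1.54 and 0.69), Cst7 (0.73) and Nkg7 (0.22) were the members that rose. The ILC1 signature split again: of 14, 2 rose, 5 fell and 7 did not pass the test (3 rose and 6 fell when adjusted over the list alone). The median was -0.27 (by library -0.77 and -0.14), with a camera adjusted p = 4.28e-11 (adjusted p = 0.637 with an estimated correlation). This negative median rested mostly on liver replicate 1. Tmem176b (-2.57), Tmem176a (-2.44), Rora (-1.59) and Cd160 (-0.41, by library -0.62 and -0.28) and Il7r fell, and Itga1 (0.59) and Il21r (0.48, by library 0.31 and 0.61) rose. Of 27 transcription factors, 0 rose, 6 fell and 21 did not pass the test (0 rose and 8 fell when adjusted over the list alone). Around their median, -0.16, camera gave an adjusted p = 6.32e-05 (adjusted p = 0.637 with an estimated correlation). Those that fell were Tcf7 (-1.99), Klf3 (-1.80), Rora (-1.59), Ikzf2 (-1.05), Klf2 (-0.83) and Maf (-0.71, by library -0.18 and -1.13). Tcf7 encodes TCF-1, a factor of early lymphoid cells. For 21 cytokine receptors, 1 rose, 5 fell and 15 did not pass the test (2 rose and 7 fell when adjusted over the list alone). The list median, -0.18 (by library -0.03 and -0.17), had a camera adjusted p = 0.0168 (adjusted p = 0.637 with an estimated correlation). Il18r1 (-1.67, by library -0.68 and -2.76) and Ifngr1 (-0.52) and Il7r fell, and Il21r rose. Among 15 NK signature genes, 1 rose, 1 fell and 13 did not pass the test. A median of 0.20 (by library 0.70 and -0.15) went with a camera adjusted p = 0.000205 (adjusted p = 0.684 with an estimated correlation). The libraries differed in the sign of this median, while Gzma rose and Klf2 fell. Among 6 Ly49 receptor genes, 1 rose, 0 fell and 5 did not pass the test (2 rose and 0 fell when adjusted over the list alone). The median was 0.22 (by library 0.59 and 0.18), with a camera adjusted p = 0.00926 (adjusted p = 0.637 with an estimated correlation). The fitted rise of Klra7 (1.06, by library 0.13 and 1.18) came from liver replicate 2. Some gene groups that can reflect handling or RNA quality differed here too, again between cells of the same libraries, and the cause was not tested. Of 28 immediate early and stress genes, 3 rose, 10 fell and 15 did not pass the test (3 rose and 11 fell when adjusted over the list alone). Around their median, -0.18, camera gave an adjusted p = 6.32e-05 (adjusted p = 0.637 with an estimated correlation). Nr4a1 (-1.14), Egr1 (-0.77) and Junb (-0.31) fell and Nr4a2 (0.59) rose. Of 26 ribosomal protein genes, 0 rose, 8 fell and 18 did not pass the test (0 rose and 11 fell when adjusted over the list alone). The list median, -0.12 (by library -0.17 and -0.07), had a camera adjusted p = 3.06e-07 (adjusted p = 0.684 with an estimated correlation). Of 13 mitochondrial mRNAs, 0 rose, 0 fell and 13 did not pass the test. A median of -0.06 (by library -0.09 and -0.04) went with a camera adjusted p = 0.266.

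In 13 cytokine and chemokine genes, 3 rose, 1 fell and 9 did not pass the test (5 rose and 3 fell when adjusted over the list alone). The median was -0.04 (by library -0.11 and 0.00), with a camera adjusted p = 0.154. Here the mean was 0.16 and the test pointed up, against the sign of the median. Ccl5 (0.38), Ccl4 (0.36) and Tnfsf8 (0.85) rose, and the fitted fall of Ifng (-0.33, by library -0.69 and -0.05) came from liver replicate 1. Other NK receptors numbered 23, of which 5 rose, 5 fell and 13 did not pass the test (9 rose and 8 fell when adjusted over the list alone). Around their median, 0.11 (by library 0.11 and 0.03), camera gave an adjusted p = 0.976. For these the mean was -0.03 and the test pointed down, against the median. Lag3 (0.49, by library 0.21 and 0.61), Cd7 (0.43), Tyrobp (0.37) and Fcer1g (0.35) rose and Klrb1b (-0.66) and Ncr1 (-0.48) fell. In homing and adhesion, 18 genes were tested, of which 3 rose, 3 fell and 12 did not pass the test (3 rose and 4 fell when adjusted over the list alone). The list median, 0.00 (by library 0.19 and -0.18), had a camera adjusted p = 0.471. Against this median, the mean was -0.10 and the test pointed down. Cd69 (0.60), Itga1 (0.59) and Itgb2 (0.32) rose and Ccr2 (-1.77), Cd9 (-0.96) and Cd44 (-0.44) fell. Of 5 T cell markers, 3 rose, 1 fell and 1 did not pass the test. Their median was 1.89 (by library -0.77 and 1.84), with a camera adjusted p = 0.256. Cd3d rose in both libraries and Cd28 fell. The fitted rises of Cd3e (2.00) and Cd8a (1.89) rest on liver replicate 2 (64 against 47 and 40 against 38 UMIs in positive and negative cells), as liver replicate 1 held 0 against 14 and 0 against 1 UMIs, too few for a direction. Of 5 dendritic cell markers, 0 rose, 3 fell and 2 did not pass the test. Their median was -2.14 (by library -2.31 and -1.28), with a camera adjusted p = 8.42e-05 (adjusted p = 0.684 with an estimated correlation). Those that fell were Cd74 (-2.25), H2-Ab1 (-2.14; 2 and 2 UMIs in Klra5-positive against 76 and 23 in negative cells) and H2-Aa, which had 1 UMI in Klra5-positive against 68 in negative cells, a ratio of 15.2 (95% counting interval 2.64 to 609). Of 4 erythroid and platelet genes, 0 rose, 0 fell and 4 did not pass the test. A median of 0.04 (by library -0.05 and 0.20) went with a camera adjusted p = 0.783. Beside these groups stood the medians of -0.18 for immediate early and stress genes and -0.12 for ribosomal protein genes.

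With the library as a block, edgeR called 113 genes higher and 167 lower among 8362 tested, and 973 had an unadjusted p under 0.05. Without the replicate block edgeR called 0 genes (258 with an unadjusted p under 0.05), DESeq2 called 22 higher and 27 lower, and after thinning 40 were higher and 74 lower. Of the genes with the largest changes, DESeq2 did not call Serpinb6a (adjusted p = 0.0560) and Hes1 (adjusted p = 0.166) and gave no adjusted p for Htra1, G0s2, Krt83, Capg, Tnfrsf25 and Ramp1. The genes G0s2, Ramp1 and Hes1 were not called after thinning. Within the Klra5-rich clusters alone, a choice made after seeing the data, 48 were higher and 56 lower, and 94 of the 280 genes were called there too. In 20 random splits of the same cells into classes of the same sizes, between 0 and 12 genes were called, with a median of 4. Only 4 of the splits had 0 calls, so the test with the block gave more false calls than its threshold allows for.

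Bulk and single-cell fold changes were then set side by side. The question was whether the Ly49E receptor in the bulk and a Klra5 UMI in the single cells go with the same transcripts. Of 8027 genes tested in both, 61 rose in both, where 4.13 were to be found by chance, and 60 fell in both, where 10.3 were; these include Gzma, Gzmb, Gzmc, Htra3 and Cd3g (bulk log2 fold change 1.86, SE 0.23; named for the bulk after its value was seen) among the rises, and Il7r, Tmem176a, Tmem176b, Tcf7, Klf3, Ccr2 and Cd28 among the falls. No gene rose in bulk and fell in the single cells by edgeR calls (6.04 by chance), and 3 did the opposite (7.06 by chance): Lgals3 (-2.10 in bulk and 0.85 in single cells), Hpse (-1.11 and 2.30) and Napsa (-1.12 and 0.53), named after their values were seen. Over all 8027 genes, passed or not, 33.2% had the bulk sign in both liver libraries and 22.7% the opposite sign in both, so that 59.4% of the 4490 genes of one sign matched the bulk, with a Spearman coefficient of 0.222 between the fitted fold changes of all 8027. Of the 816 bulk calls tested in the single cells, 460 (56.4%) had the bulk sign in both liver libraries, 92 (11.3%) had the opposite sign in both, and in 264 the libraries differed in sign. Among the 552 of one sign, 83.3% matched the bulk (exact two-sided binomial p = 7.95e-60 across genes, against equal odds of either sign). As 59.4% of all genes of one sign matched, this p overstates how far the bulk calls stand out. Spearman's coefficient across the 816 genes, which are not independent replicates, was 0.611. Taken by library, 71.4% of the signs matched in liver replicate 1 and 73.7% in liver replicate 2.

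**Figure D3:**
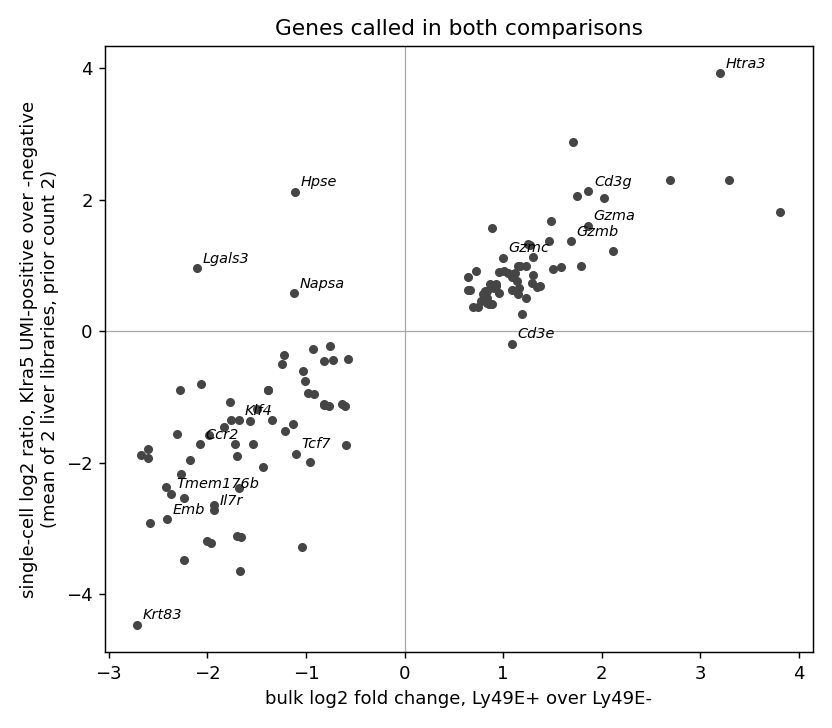
Each point is 1 of 124 genes called in both comparisons, with the bulk log2 fold change of Ly49E+ over Ly49E- ILC1s on the horizontal axis and the mean single-cell log2 ratio of the 2 liver libraries (Klra5 UMI-positive over UMI-negative ILC1-like cells, prior count 2) on the vertical axis. Of these genes 121 had the same sign by their fitted fold changes, the exceptions being Lgals3, Hpse and Napsa; Cd3e lies below 0 because liver replicate 1 held 0 against 14 UMIs of it, where the ratio depends on the prior count.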

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

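The tests of damaged cells and of a rise of every ribosomal protein mRNA were chosen after the result was seen. In liver replicate 2, 34.09% of the kept cells (1122 of 3291; exact 95% interval 32.47 to 35.74) lay in a pair of unnamed clusters whose pooled UMIs were 62.5% from ribosomal protein genes, against 24.6% in the named clusters, and entered no comparison. Cells above 50% ribosomal UMIs numbered 1077 of 3291 in this library (32.73%, 31.12 to 34.36), and 0 in liver replicate 1 and in the spleen, which allows up to 0.165% and 0.141%. These barcodes had a median of 3290 UMIs over 632.5 genes, against 3971 over 1546 in the named clusters, and a Klra5 UMI in 3.12% of them. Malat1 stood 27.6 times lower and Rps2 12.0 times lower than in the named clusters, genes chosen after their values were seen.

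Free RNA in the droplets was argued against, since the ribosomal share of these barcodes lay 31.93 points above the 30.6% of barcodes under 100 UMIs. Damaged cells that lost cytoplasmic RNA were argued against by a median mitochondrial share of 0.0926%, against 1.43% in the named clusters. Mouse cells that made more of every ribosomal protein mRNA were argued against, since 7 of the 26 listed genes were over 4 times lower while 14 were over 2 times higher. Transcripts whose sequence differs from the mouse reference stay open as a candidate explanation, because 5 ribosomal pseudogenes took 1.81 times their share in the named clusters, between the bounds of 1.5 and 3 set for the test. The differing processing by the authors applied to the whole library, yet its named clusters held 24.6% ribosomal UMIs against 62.5% in these barcodes. This argues against processing as the only cause, while processing together with another cause stays open. No other biological explanation was tested.

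In the spleen, 18.24% of the kept cells (388 of 2127) formed a cluster with NK markers, led by Thy1, Emb and Cd3d, that stayed unnamed and entered no comparison. With these cells added, the NK-like cells of the spleen numbered 1984, and edgeR called 0 genes between liver and spleen (168 with an unadjusted p under 0.05). The median log2 fold change of the ILC1 signature went from 1.38 to 0.75.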

How the results depend on the processing

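The spleen cluster counted as NK-like, the Klra5-rich clusters alone and the bulk genes at 20 CPM or more in ILC1-like cells were settings chosen after seeing the data. Among results that answer a comparison, 168 values kept their direction and side of the threshold or moved less than their spread, 22 lost the call or, for counts of called genes, fell past a set bound, 15 moved, 1 became a call and 1 called value reversed. The 168 include counts of called genes within that bound. For fold changes and list medians with a replicate left out, the spread came from the very values compared. Most of these held by construction, which is no sign of stability. For single named genes, 518 held in this sense, 37 lost the call and 52 moved. The count of ILC1-like against NK-like genes fell to 924 with DESeq2 and to 332 with no replicate block. The count between Klra5 classes was 49 with DESeq2, 0 with no replicate block (edgeR; 258 with an unadjusted p under 0.05), 114 after thinning to 2000 UMIs and 104 in the Klra5-rich clusters alone. Between liver and spleen 1 gene was called at resolution 0.5. Thinning and the Klra5-rich clusters leave fewer UMIs or cells, and for the other settings the cause was not tested. Of the bulk calls, 510 lay among the genes at 20 CPM or more in ILC1-like cells, where fewer genes are counted. In the bulk, no filter on low counts removed no gene, so that setting says nothing.

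With an estimated correlation, the adjusted p of the bulk lists was 0.7069 for the NK signature, cytotoxic effectors, cytokines and chemokines, other NK receptors, cytokine receptors, interferon-stimulated genes, macrophage, neutrophil, dendritic cell, hepatocyte, endothelial and erythroid lists, 0.7578 for proliferation and 0.8025 for ribosomal protein genes. With 1 residual degree of freedom that test could hardly have called any list, so these values cannot decide. The cytokine list had an adjusted p of 0.0502 with RLE factors. Leaving out each Ly49E- replicate leaves no residual degree of freedom, so fold changes alone were compared. List medians then ranged from 0.39 to 0.54 for other NK receptors, -0.28 to -0.17 for homing, -0.30 to -0.19 for transcription factors, 0.0103 to 0.203 for plasma cell markers, -1.60 to -1.57 for dendritic cell markers, -2.57 to -2.47 for endothelial markers and -0.65 to 1.39 for erythroid and platelet genes, which reversed. The medians of 4 lists that were not called changed sign too: -0.22 to 0.20 for Ly49 receptors, -0.06 to 0.24 for immediate early and stress genes, -0.13 to 0.30 for mitochondrial mRNAs and -0.08 to 0.23 for B cell markers. The cause was not tested.

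The ILC1-like share of liver replicate 1 was 43.6% at resolution 0.5, 30.7% at resolution 2 and 28.4% with classes per cell by marker balance, which gave 42.4% in liver replicate 2 and 2.73% in the spleen. With a fixed minimum of 1000 UMIs the spleen share was 0, as no cluster was named ILC1-like. Thinned to 2000 UMIs, Klra5 shares were 10.1% and 17.7% in ILC1-like cells of liver replicates 1 and 2 and 1.97% in NK-like cells of liver replicate 2, so depth limits how many Klra5-bearing cells are seen.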

Other observations

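The tests of an interferon difference that goes with Ly49E and of free globin mRNA were chosen after the result was seen. Between ILC1-like and NK-like liver cells, interferon-stimulated genes differed: of 28, 16 rose, 3 fell and 9 did not pass the test (17 rose and 3 fell when adjusted over the list alone). The median was 0.77, with a camera adjusted p = 3.28e-06 (adjusted p = 0.442 with an estimated correlation). Isg15 (1.46) and Stat1 (1.01) were among those that rose. Of 16 proliferation genes, 0 rose, 4 fell and 12 did not pass the test. Around their median, -0.09 (by library -0.11 and -0.25), camera gave an adjusted p = 0.133. Stmn1 (-3.01) fell most. Of 3 fetal haematopoiesis genes, 1 rose, 2 fell and 0 did not pass the test. The list median, -0.68 (by library -0.91 and -0.18), had a camera adjusted p = 0.467.

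Between Klra5 classes of ILC1-like cells, 25 interferon-stimulated genes were tested, of which 0 rose, 2 fell and 23 did not pass the test (0 rose and 3 fell when adjusted over the list alone). A median of 0.08 (by library -0.48 and 0.16) went with a camera adjusted p = 0.947. The libraries differed in the sign of this median, the mean of -0.19 opposed the fitted median and the test, and Ifi27l2a (-2.15) and Gbp3 (-1.85) fell. Of 13 proliferation genes, 0 rose, 0 fell and 13 did not pass the test. The median was 0.04 (by library -0.14 and 0.09), with a camera adjusted p = 0.947. Here too the mean, -0.06, had the opposite sign. Of 23 proliferation genes in the bulk, 0 rose, 5 fell and 18 did not pass the test. Around their median, -0.33 (by library -0.24 and -0.55), camera gave an adjusted p = 0.0496 (adjusted p = 0.758 with an estimated correlation). Mki67 (-1.35) and Top2a (-1.36) fell, beside the lower macrophage markers.

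In the bulk, macrophage markers and interferon-stimulated genes were lower in the Ly49E+ library. A candidate explanation is RNA of macrophages in the Ly49E- libraries: 23 other macrophage genes had a median log2 fold change of -2.57, and 21 of them fell, among them the abundant Psap (983 against 3444 CPM) and Ctss (115 against 748 CPM), named after their values were seen, although the libraries are labelled as sorted ILC1s, and a sort would remove macrophages. Such cells may have been peritoneal, since Gata6, a transcription factor of peritoneal macrophages, had a log2 fold change of -2.07 (SE 0.45; 1.36 against 5.04 and 6.45 CPM), which rests on a single gene outside the lists. An interferon gene difference that goes with Ly49E in liver ILC1s in general stays open: between the Klra5 classes the median log2 fold change of 25 of these genes was 0.0804, but -0.48 in liver replicate 1 (quartiles -0.93 and 0.0250; 8 genes had at most 3 UMIs in Klra5-positive cells) and 0.16 in liver replicate 2 (quartiles -0.0872 and 0.38), against -0.82 in the bulk. A difference between the sorted populations of the bulk mice, aged 5 weeks, stays open too and was not tested.

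Globin mRNA stood higher in NK-like cells of the liver than of the spleen. Free globin mRNA from red cells may account for it: NK-like cells held 0.933 times the globin CPM of ILC1-like cells in liver replicate 2 and 0.989 times in liver replicate 1. Globin stood at 2376 and 400.1 CPM in NK-like cells of the liver libraries and at 37.7 CPM in the spleen. Barcodes under 100 UMIs held 173.5 and 19.8 times the globin CPM of those of the spleen library. No biological explanation was tested.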
